A study of Homo sapiens with 2 samples.

How the data were processed

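Poly(A)-selected RNA was sequenced from 2 established human small cell lung cancer (SCLC) lines, with 1 library per line and no treatment. Per the labels, H446 came from a pleural effusion and carries the phenotype of chemosensitivity, and SHP77 carries that of chemoresistance. Total RNA was extracted, mRNA was captured with oligo dT beads, and libraries were made with a NEBNext Ultra RNA kit and sequenced as read pairs on an Illumina instrument, per the labels' protocols. The labels do not say whether reads were counted by strand, so reads of a gene and of an overlapping antisense gene may be mixed.

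The deposited table holds 45006 RefSeq mRNA transcripts with the read count and the RPKM (reads scaled by transcript length and library total) of each library, and a transcript length in bases. The counts were made by the authors and are whole numbers with no normalization. The submitters' processing notes name bcl2fastq, HISAT2 2.1.0, HTSeq 0.11.2 and the genome build hg19, without saying which step each was used for. The RPKM values were made by the authors from the same counts and lengths, since the values imply 1 fixed library total per column, 104898768 for H446 and 90210293 for SHP77. These totals exceed the sums of transcript counts, 96721302 and 81919173.

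The rows of a gene share reads. Among 6958 genes with several transcripts that each had at least 50 counts in H446, the highest isoform count was a median of 1.14 times the lowest. Summing the rows of a gene would therefore count reads repeatedly, and each gene was represented by the transcript with the most counts over both libraries. This gave 19225 genes with 40069722 counts in H446 and 35485317 in SHP77. Names in the form of dates stood for 25 genes on 103 rows, and these were replaced by the symbol of the RefSeq accession in a gene table of assembly GRCh38.p14, in which 98.6% of the accessions were found. That table also gave the order of neighbouring genes, and none of its coordinates are printed, because its assembly is not the one used for the counts. Symbols of the list members MRE11 and ERO1A were matched through their older names.

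Counts were scaled to CPM, the count relative to the library total, with TMM factors from edgeR 4.0.16 in R 4.3.3. Genes with a CPM of at least 1 in at least 1 library were tested against size rules, and the fold change was log2((CPM + 1)/(CPM + 1)), SHP77 over H446, which understates the difference of low genes. With 1 library per group no p-value can be had, and none is given. A gene was called higher in a line when the fold change was 2 or more. Ratios of CPM without the pseudocount carry exact (Clopper-Pearson) 95% intervals of the read share between the libraries. These intervals, and the floor of 3 counts used for genes at 0, cover counting error only, since the reads carried no molecular identifiers. A floor of 3 counts equals 0.0776 CPM in H446 and 0.0816 CPM in SHP77.

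Before the data were examined, 40 gene lists and 7 lists of cell-type markers were fixed. A list's median fold change over its tested members was placed among 10000 random lists of the same size, matched on mean expression in 20 bins, and the list was said to stand apart below percentile 2.5 or above percentile 97.5. Lists with fewer than 5 tested members have values only. The percentiles describe these libraries and are not tests of the phenotypes. Lists overlap, so a gene can count in several of them.

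The rule for named genes, also fixed beforehand, took the 12 largest fold changes per direction among protein-coding genes with at least 10 CPM in the higher library, 10 lineage regulators, 10 drug-response genes, the 5 most abundant genes of each library, and up to 4 members of each list with the largest absolute fold changes, plus the largest of the opposite direction. Y-linked genes were left out, and some genes that the rule takes are not reported here. Genes with near-identical copies are uncertain, because the counting of reads that match several copies is not described in the sources used here. This holds for class I HLA genes, histones, ribosomal proteins, metallothioneins, keratins, MAGE genes, IFITM genes and for FTH1, FTL, GAPDH, ACTB and EEF1A1, which have processed pseudogenes. HLA genes also differ between people, and reads of alleles unlike the reference can be lost. Mitochondrially encoded genes were to be used as a measure of RNA quality, but 0 of the 13 were matched, and they are not analysed here.

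Transcript GC content came from the GENCODE release 29 transcript paired with the RefSeq accession, or otherwise with the symbol, and 99.8% of the tested genes had a value. Trends of the fold change on GC content and on length were removed by lowess regression with a span of 0.3. Self-tests used counts simulated from the mean profile and the totals of the 2 libraries for the SHP77 over H446 comparison, in which 13493 genes were tested and 200 were changed. Of the 100 genes changed 3-fold, 98% passed the 2-fold rule in the right direction, and of the 100 genes changed 8-fold, 100% did. No unchanged gene passed among 13268, and the 95% counting intervals held the simulated ratio for 95.3% of genes. A simulated list of 25 genes shifted by 1.5-fold reached percentile 100, and an unshifted list of 20 genes percentile 87.8. Most simulated genes were unchanged, so random lists spread little there. In the data, the central 95% of random lists matched to a fixed list of 25 genes ran from -0.78 to 0.80 in log2. The self-test therefore does not show that a 1.5-fold shift would stand apart in the data. In a second simulated set with a GC trend, a Spearman correlation of 0.94 over 13505 genes was reduced to -0.0054. The simulation holds counting error only, so it describes the calculation and not the variation between cultures.

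The alternatives were plain library totals, DESeq2 1.42.0 size factors and upper-quartile scaling, other filters and pseudocounts, the deeper library thinned, ribosomal protein genes left out, a 4-fold rule, protein-coding rows alone, other matchings of the random lists and list means. Further alternatives were chosen after seeing the data: the longest transcript per gene, the sum over transcripts, the library totals implied by the authors' RPKM, GC and length trends removed, and genes at 0 placed at their bound. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures were drawn with matplotlib 3.10.9.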

Results

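The data compare the transcriptomes of 2 SCLC lines, H446 and SHP77. SCLC is a fast-growing lung cancer, usually of neuroendocrine character, that often responds to chemotherapy at first and then relapses. H446 was labelled chemosensitive and derived from a pleural effusion, and SHP77 was labelled chemoresistant and derived from a lung tumour. Each line contributed 1 untreated poly(A) RNA-seq library, with 40069722 gene-level counts in H446 and 35485317 in SHP77. Of 19225 genes, 4166 had 0 counts in H446 and 3026 had 0 counts in SHP77. The comparison has no replicate check, and because phenotype, donor and site of origin differ together, it compares these libraries and not chemosensitivity with chemoresistance.

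Neuroendocrine and secretory granule genes were higher in SHP77, and matrix, YAP and TAZ target and interferon-stimulated genes were higher in H446. VGF, a neuropeptide precursor, was the most abundant gene of SHP77 at 18355 CPM against 3.08 CPM in H446, a ratio of 5962 (95% counting interval 4982 to 7197). CALCA, which encodes calcitonin and calcitonin gene-related peptide, was 5051 times as abundant in SHP77 (3737 to 7009). BASP1, a membrane protein of growing axons, had the largest log2 fold change in the other direction on the scale with a pseudocount of 1, at 2147 CPM in H446 and 0.408 CPM in SHP77, a ratio of 5265 (3192 to 9407). FOLR1, a folate receptor, was 2212 times as abundant in H446 (1318 to 4046), and the hyaluronan receptor CD44 was 1688 times as abundant (1039 to 2953).

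Among 13896 tested genes, 3910 (28.1%) were at least 2-fold higher in SHP77, 3608 (25.96%) were at least 2-fold higher in H446, and 6378 lay within 2-fold. The counting interval lay wholly beyond 2-fold for 3759 and 3429 of them. At least 4-fold, 1926 genes were higher in SHP77 and 1602 in H446. Across the tested genes, which are not independent replicates, log2(CPM + 1) of the 2 libraries correlated with a Pearson r of 0.60 and a Spearman rho of 0.63. There were 205 genes with 0 counts in H446 and at least 10 CPM in SHP77, and 77 with 0 counts in SHP77 and at least 10 CPM in H446. The median log2 fold change of all tested genes was 0.03 with TMM scaling and 0.14 with plain library totals, so directions are relative to that choice.

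**Figure D1:**
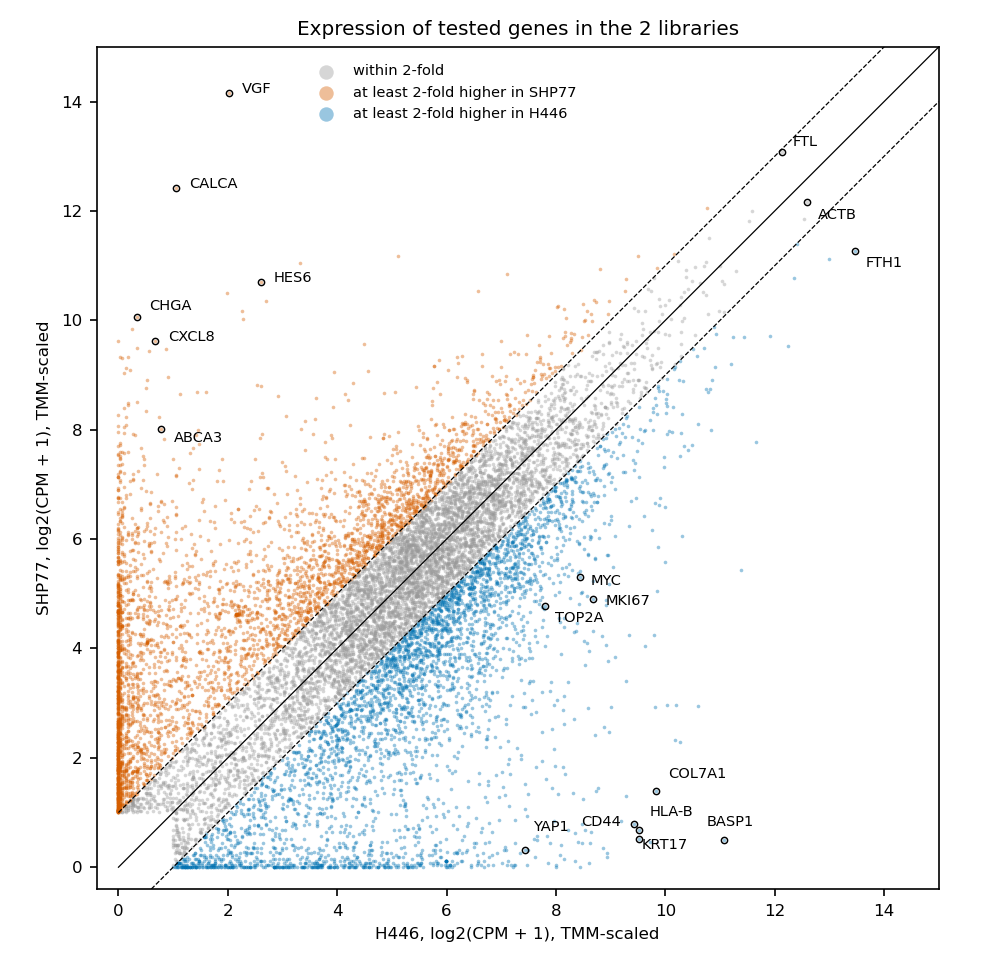
Each point is a tested gene, with log2(CPM + 1) in H446 on the horizontal axis and in SHP77 on the vertical axis, and dashed lines mark 2-fold. The 3910 genes in orange were at least 2-fold higher in SHP77 and the 3608 in blue at least 2-fold higher in H446, with VGF at 18355 CPM in SHP77 and BASP1 at 2147 CPM in H446 far from the diagonal.

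The other genes named for the largest differences towards SHP77 were ranked on the same scale. The granins CHGA and CHGB, matrix proteins of secretory granules, reached 1075 and 786 CPM in SHP77. H446 had 10 counts of CHGA, a ratio of 4155 (2259 to 8664), and 0 of CHGB. Against the floor of 3 counts CHGB was 10133-fold higher in SHP77, and the lower 95% limit of its ratio was 8240. The prohormone convertase PCSK2 (646 CPM) had 1 count in H446, a ratio of 24981 (4483 to 986727), and the granule protein PTPRN (633 CPM) had 2, a ratio of 12227 (3384 to 100969). The axonal kinesin KIF1A reached 915 CPM in SHP77, the synaptic complexin CPLX2 645 CPM and the stathmin STMN3 522 CPM, against 7, 5 and 3 counts in H446. CXCL8, a neutrophil-attracting chemokine and not a neuroendocrine gene, was also in this set, with 786 CPM in SHP77 and 0.595 CPM in H446.

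The largest differences towards H446, ranked likewise, included COL7A1, FBLN1, KRT17 and HLA-B. COL7A1, the anchoring-fibril collagen, had 910 CPM in H446 and 1.63 CPM in SHP77, and the matrix glycoprotein FBLN1 had 583 and 0.788 CPM. KRT17, a basal keratin, had 684 and 0.734 CPM, and HLA-B, a class I antigen-presenting molecule, had 732 and 0.598 CPM. IGFBP7, a secreted binding protein, had 489 CPM in H446 and 5 counts in SHP77. RCN1, a calcium-binding protein of the endoplasmic reticulum, had 464 CPM and 10 counts. LY6K had 387 CPM and 2 counts, a ratio of 7112 (1969 to 58735), and the protease inhibitor SPINK6 had 346 CPM and 0 counts. Against the floor used for genes at 0, SPINK6 was 4243-fold higher in H446, and the lower 95% limit of its ratio was 3450.

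The lines differed in lineage regulators of SCLC. INSM1, a zinc-finger factor of neuroendocrine cells, was at 559 CPM in SHP77 with 4 counts in H446. YAP1, the Hippo pathway coactivator, was at 172 CPM in H446 and 0.245 CPM in SHP77. REST, a repressor of neuronal genes, was 19.6 times as abundant in H446 (15.4 to 25.3), at 37.3 against 1.90 CPM. NEUROD1 had 4 counts in SHP77 and 0 in H446, ATOH1 had 14 and 0, and POU2F3 had 0 in SHP77 and 10 in H446, so none of these reached 1 CPM.

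Of the MYC family, MYC was 8.97 times as abundant in H446 (8.49 to 9.48), at 347 against 38.7 CPM. MYCL was at 7.69 CPM in SHP77 and 5 counts in H446, a ratio of 59.5 (25.2 to 184.6). MYCN had 1 count in SHP77 and 0 in H446.

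Of the 19 tested lineage regulators, 13 were at least 2-fold higher in SHP77, 4 in H446, and 2 lay within 2-fold. The median log2 fold change was 3.11, at percentile 100 of the random lists. FOXA2, a factor of endodermal lineages, was at 140.2 CPM in SHP77 and 0 counts in H446. Against the floor of 3 counts it was 1806-fold higher in SHP77, and the lower 95% limit of its ratio was 1468.

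A published neuroendocrine score was used with its members as remembered, not taken from the source. It may have been built on panels of lines that held these 2, so its percentiles are not independent support. Of its 24 tested high genes, 23 were higher in SHP77 and 1, SH3GL2, was higher in H446 (16.5 CPM and 1 count). Their median log2 fold change was 6.29, or 6.80 with genes at 0 placed at their bound, at percentile 100. Of the 25 low genes of that score, 22 were higher in H446, 2 in SHP77 and 1 lay within 2-fold, with a median of -4.85, or -5.29 at the bounds, at percentile 0. Among them were the scaffold AHNAK (1170 and 6.77 CPM), CYR61 (161.8 and 0.190 CPM) and S100A10 (193.1 and 0.435 CPM), given for H446 and then SHP77. PLAU, the urokinase plasminogen activator, went the other way (3.39 and 19.7 CPM).

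Of 25 genes of secretory granules and synaptic vesicles, 23 were higher in SHP77, 1 in H446 and 1 lay within 2-fold. The median was 6.996, or 7.24 at the bounds, at percentile 100.

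**Figure D2:**
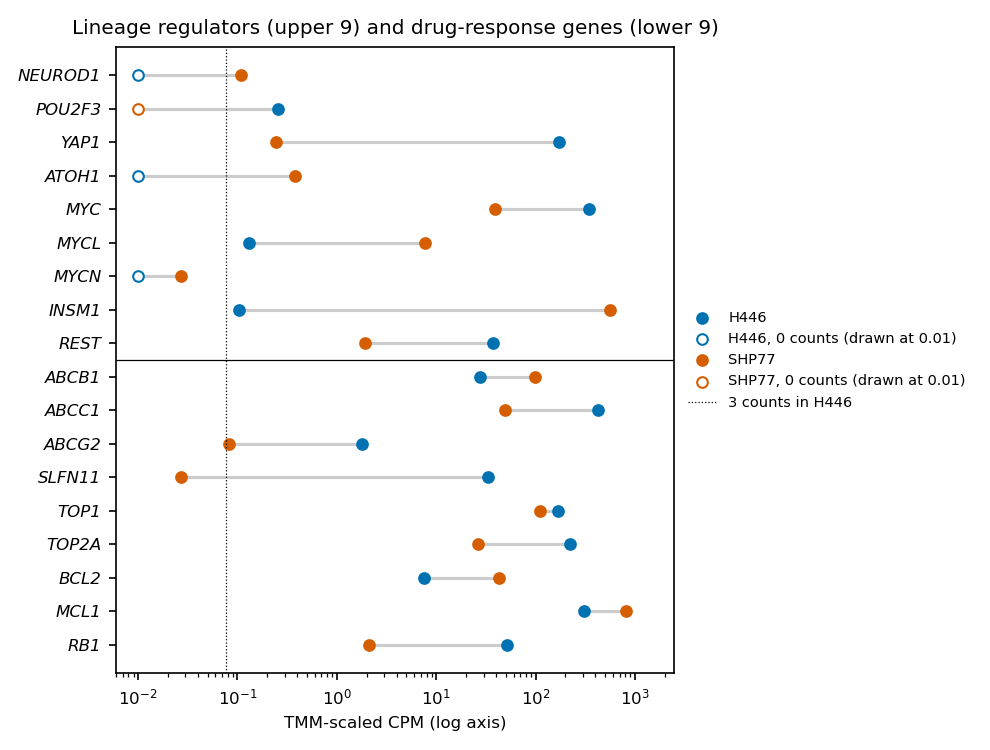
Points give the TMM-scaled CPM of H446 (blue) and SHP77 (orange) on a log axis for 9 lineage regulators and 9 drug-response genes, with open symbols for 0 counts and a dotted line at 3 counts in H446. INSM1 lies far to the right in SHP77 (559 CPM), and YAP1 and SLFN11 in H446 (172 and 33.5 CPM).

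In the Notch pathway, through which neighbouring cells restrain neuroendocrine differentiation, 14 of 23 tested genes were higher in SHP77, 6 in H446 and 3 lay within 2-fold. The median was 2.31, at percentile 99.99. DLL3, an inhibitory ligand and drug target in SCLC, was at 709 CPM in SHP77 and 0.828 CPM in H446, and HES6, an inhibitor of HES1, was at 1674 and 5.12 CPM. The glycosyltransferase MFNG (139.3 CPM) and the ligand DLL1 (58.8 CPM) had 0 counts in H446. The receptor NOTCH3 was higher in H446, at 133.5 against 1.495 CPM.

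YAP and TAZ targets were mostly higher in H446, with 18 of 22 genes, against 3 higher in SHP77 and 1 within 2-fold. The median was -2.64, or -3.04 at the bounds, at percentile 0. The receptor kinase AXL was at 339.5 CPM in H446 and 0.381 CPM in SHP77. IGFBP3 was at 67.3 CPM with 3 counts in SHP77, and MYOF at 320.6 and 5.52 CPM. GADD45A, a stress-response gene, was higher in SHP77 (31.3 and 184.5 CPM). In the Wnt target list, 8 of 17 genes were higher in SHP77, 5 in H446 and 4 lay within 2-fold (median 0.75, percentile 76.6). WNT5A, a non-canonical ligand, was at 424 CPM in H446 and 1.63 CPM in SHP77. FZD7 and the inhibitor DKK1 were at 15.52 and 15.005 CPM in H446, with 3 and 0 counts in SHP77, and LEF1 was at 16.6 CPM in SHP77 with 2 counts in H446.

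Mesenchymal genes were higher in H446 for 12 of 22, in SHP77 for 4, and within 2-fold for 6 (median -1.11, percentile 0.35). With the GC and length trends removed the list no longer stood apart, with 9 higher in H446, 2 in SHP77 and 11 within 2-fold (median -0.57, percentile 7.32). VIM, the intermediate filament of mesenchymal cells, was at 1547 CPM in H446 and 6.69 CPM in SHP77, TGFBI at 897 and 6.58 CPM, and TWIST2 at 23.3 CPM with 2 counts. SNAI2 was higher in SHP77 (9.78 and 55.1 CPM). Of 26 extracellular matrix genes, 15 were higher in H446, 4 in SHP77 and 7 lay within 2-fold (median -1.29, percentile 0.04). FBN1, the main microfibril protein, was at 621.8 and 1.47 CPM in H446 and SHP77, COL4A1 at 260.4 and 1.52 CPM, FBN2 at 253.2 and 2.61 CPM, and the basement membrane proteoglycan HSPG2 at 515.9 and 6.58 CPM. TNC, tenascin C, was higher in SHP77 (1.97 and 90.4 CPM).

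Epithelial genes split. Of 18 tested, 10 were higher in SHP77, 7 in H446 and 1 lay within 2-fold, with a median of 1.32 at percentile 99.5 but a mean of 0.35 at percentile 66.4. Another 4 stayed below 1 CPM in both lines, among them CDH1 (0.336 and 0.353 CPM in H446 and SHP77), ESRP1 and GRHL2. With a filter at 5 CPM the median was 1.03 at percentile 96.4, inside the random range. The adhesion molecule EPCAM (5.20 and 146.2 CPM), the protease inhibitor SPINT1 (4.63 and 176.3 CPM) and the tight-junction protein CLDN3 (1.53 and 44.5 CPM) were higher in SHP77, whereas KRT7, a simple-epithelial keratin, was 62.5 times as abundant in H446 (59.5 to 65.8).

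Class I antigen presentation and interferon-stimulated genes were lower in SHP77. Of 18 antigen presentation genes, 13 were higher in H446, 0 in SHP77 and 5 lay within 2-fold (median -1.78, percentile 0.01). HLA-C was at 468 and 4.89 CPM in H446 and SHP77, HLA-F at 55.3 and 0.924 CPM, and NLRC5, their transcriptional activator, at 104.3 and 4.08 CPM, while the chaperone CALR was at 1491 and 2017 CPM. Of 27 interferon-stimulated genes, 25 were higher in H446, 1 in SHP77 and 1 lay within 2-fold (median -3.29, percentile 0). The antiviral GTPase MX1 was at 236.4 and 0.353 CPM, IFI44L at 72.2 CPM and 2 counts, the DNA sensor IFI16 at 99.8 and 0.652 CPM and IFIT3 at 54.4 and 0.190 CPM. ISG20, an exonuclease, was higher in SHP77 (5.41 and 29.1 CPM).

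NF-kB and inflammatory genes went the opposite way from the interferon list. Of 20, 11 were higher in SHP77, 3 in H446 and 6 lay within 2-fold (median 1.63, percentile 99.99). Besides CXCL8, the cytokine LIF was at 10.8 CPM in H446 and 241.2 CPM in SHP77, CXCL2 at 8.51 and 92.3 CPM, and TNF at 0 counts and 12.2 CPM. BIRC3, an inhibitor of apoptosis, was higher in H446 (8.36 and 0.707 CPM).

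Genes of mitosis were lower in SHP77. Of 26 G2/M genes, 21 were higher in H446, 0 in SHP77 and 5 lay within 2-fold, and the median log2 fold change was -2.52 at percentile 0. The kinetochore proteins CENPE (44.0 and 0.652 CPM) and CENPF (236.9 and 8.32 CPM), the proliferation antigen MKI67 (409 and 29.03 CPM) and the checkpoint kinase TTK (29.6 and 2.15 CPM) differed most, in H446 and SHP77 respectively. By contrast, 18 of 24 G1/S genes lay within 2-fold, 6 were higher in H446 and 0 in SHP77, and their median of -0.17 was at percentile 36.0. The helicase subunits MCM6 (191.9 and 48.8 CPM) and MCM5 (271.0 and 102.5 CPM) and the ribonucleotide reductase subunits RRM1 (272.1 and 69.98 CPM) and RRM2 (164.6 and 67.0 CPM) were higher in H446, and GINS2 was at 45.7 and 89.7 CPM. Cell cycle inhibitors and cyclins D were higher in H446 for 8 of 18, in SHP77 for 3 and within 2-fold for 7 (median -0.74, percentile 3.9). RB1, the tumour suppressor commonly lost in SCLC, was 24.4 times as abundant in H446 (19.4 to 31.1), at 51.1 against 2.09 CPM. RBL1 (36.7 and 3.40 CPM) was also higher in H446, and the inhibitor CDKN2D in SHP77 (3.44 and 34.9 CPM).

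The fold change also followed the composition of the transcripts. Across the genes, its Spearman correlation was 0.28 with GC content and -0.21 with transcript length. The 1387 genes poorest in GC, with a median of 37.6%, had a median log2 fold change of -0.92, and the 1387 richest, with 64.9%, had 0.73. The 1387 shortest, with a median length of 994 bases, had 0.53, and the 1387 longest, with 8507 bases, had -0.91. The median GC content of the tested genes was 49.99%, against 44.6% for the G2/M list, 42.4% for the homologous recombination list and 59.1% for the Notch list. With both trends removed, 3438 genes were at least 2-fold higher in SHP77 and 3361 in H446, and 18 of the 20 lists that stood apart kept that call. The G2/M list then had 25 of 26 genes higher in H446, with a median of -2.14 at percentile 0. The mesenchymal list, with a median of -0.57 at percentile 7.32, no longer stood apart.

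**Figure D3:**
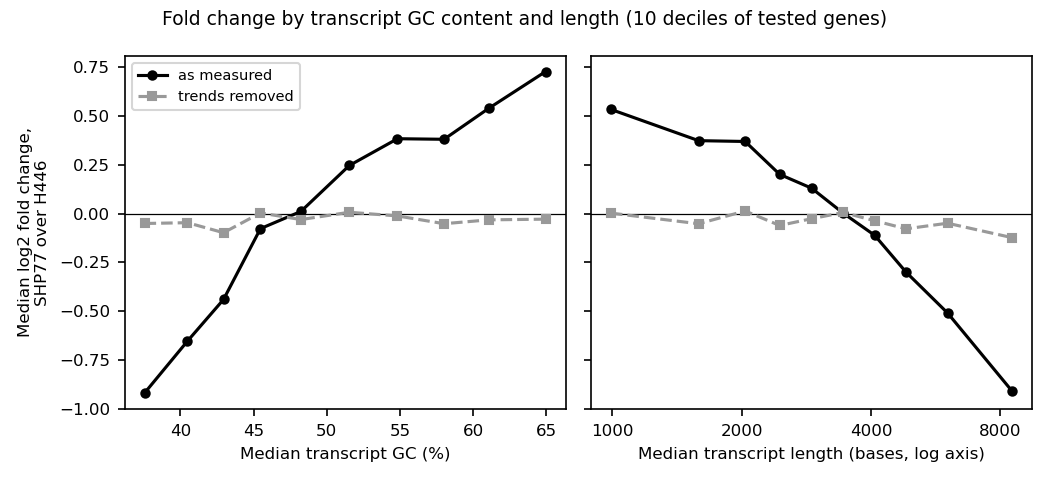
The median log2 fold change, SHP77 over H446, is plotted for 10 equal groups of tested genes ordered by transcript GC content (left) or by transcript length on a log axis (right), as measured (circles) and with both trends removed (squares). As measured, it runs from -0.92 to 0.73 with GC content and from 0.53 to -0.91 with length.

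Genes of drug response differed in both directions. ABCB1, the multidrug efflux pump P-glycoprotein, was 3.63 times as abundant in SHP77 (3.39 to 3.90), at 99.5 against 27.4 CPM. ABCC1, another efflux pump, was 8.61 times as abundant in H446 (8.20 to 9.04), at 421 against 49.0 CPM. ABCG2 was low in both, with 69 counts in H446 and 3 in SHP77, a ratio of 21.9 (7.18 to 108.7), and its log2 fold change of -1.36 became -0.78, within 2-fold, with the trends removed. SLFN11, which blocks replication under stress and is linked to sensitivity to DNA-damaging drugs, was at 33.5 CPM in H446 and 1 count in SHP77, a ratio of 1230 (220.4 to 48637). TOP2A, the target of etoposide, was 8.35 times as abundant in H446 (7.81 to 8.93), and TOP1, the target of topotecan, 1.51 times (1.45 to 1.57). TOP2A is also on the G2/M list, where its log2 fold change was -3.01 and the list's median -2.52. BCL2 was 5.69 times as abundant in SHP77 (5.02 to 6.47) and MCL1 2.65 times (2.59 to 2.70), both inhibitors of apoptosis.

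Of 13 drug efflux transporters, 3 were higher in SHP77, 6 in H446 and 4 lay within 2-fold, and the median of -0.71 at percentile 6.84 did not stand apart. ABCA3, a lipid transporter of alveolar cells, was at 256.7 CPM in SHP77 and 0.724 CPM in H446, while ABCC3 (188.9 and 13.1 CPM) and the vault protein MVP (192.1 and 28.1 CPM) were higher in H446. Of 22 genes tied to platinum and topoisomerase drugs, 13 were higher in H446, 1 in SHP77 and 8 lay within 2-fold (median -1.23, percentile 0.14). The metallothionein MT1E was at 44.0 CPM and 1 count, the cation transporter SLC22A3 at 18.3 CPM and 1 count and the checkpoint kinase ATR at 51.97 and 3.13 CPM in H446 and SHP77. ATP7B, a copper exporter, was higher in SHP77 (1.76 and 10.8 CPM).

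Among DNA repair lists, homologous recombination and Fanconi genes stood apart, with 15 of 28 higher in H446, 3 in SHP77 and 10 within 2-fold (median -1.47, percentile 0.03). With the GC and length trends removed the median was -0.86 at percentile 0.53. PALB2 (31.8 and 1.98 CPM), RAD50 (74.6 and 6.01 CPM), FANCM (12.5 and 0.979 CPM) and BRIP1 (11.8 and 0.979 CPM) were higher in H446, and FANCF in SHP77 (10.9 and 48.7 CPM). Nucleotide excision repair genes lay within 2-fold for 16 of 25, with 8 higher in H446 and 1 in SHP77 (median -0.46, percentile 12.9). ERCC6 (35.8 and 1.33 CPM), GTF2H1 (51.2 and 10.98 CPM) and DDB2 (56.7 and 16.4 CPM) were higher in H446. ERCC4 (30.4 and 12.1 CPM) was too, and RPA3 was higher in SHP77 (26.1 and 58.1 CPM), but both lay within 2-fold with the trends removed, where the log2 fold change of ERCC4 went from -1.26 to -0.23 and that of RPA3 from 1.12 to 0.96, just under the rule. For mismatch repair and end joining, 13 of 20 genes lay within 2-fold, 7 were higher in H446 and 0 in SHP77 (median -0.63, percentile 6.41). The polymerase POLQ was at 24.4 and 2.12 CPM and POLB at 18.0 and 36.4 CPM. XRCC5 (494.1 and 196.5 CPM), DCLRE1C (13.6 and 5.08 CPM) and MSH3 (29.1 and 11.8 CPM) lay within 2-fold with the trends removed. The log2 fold change of XRCC5 went from -1.33 to -0.99, just under the rule, that of DCLRE1C from -1.26 to -0.76 and that of MSH3 from -1.23 to -0.72.

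Apoptosis genes did not stand apart. Of 9 anti-apoptotic genes, 3 were higher in SHP77, 2 in H446 and 4 lay within 2-fold (median 0.09, mean -0.014, percentile 60.4), and CFLAR, at 28.4 and 11.5 CPM, lay within 2-fold with the trends removed (log2 -1.23 before and -0.32 after). Of 23 pro-apoptotic genes, 8 were higher in SHP77, 7 in H446 and 8 lay within 2-fold (median 0.11, mean -0.31, percentile 61.5), and with the trends removed 5 and 6 with a median of -0.08. All of the named death receptors were higher in H446: TNFRSF10B at 171.1 and 1.09 CPM, TNFRSF10A at 23.1 and 0.190 CPM and FAS at 16.6 and 0.109 CPM. BMF, a BH3-only protein, was higher in SHP77 (9.91 and 131.6 CPM).

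Of 29 NRF2 and glutathione genes, 8 were higher in SHP77, 10 in H446 and 11 lay within 2-fold (median 0.02, percentile 58.8). GPX2, a glutathione peroxidase, was at 0.129 and 191.8 CPM in H446 and SHP77 and GSTA4 at 4.14 and 32.7 CPM, whereas the cystine transporter SLC7A11 (263.6 and 31.8 CPM) and MGST1 (257.7 and 49.3 CPM) were higher in H446. Stem cell and aldehyde dehydrogenase genes were evenly split, 6 and 6 of 15 with 3 within 2-fold (median -0.07, percentile 30.7, and 0.39 with the trends removed). Beside CD44, ALDH3A1 was higher in H446 (70.0 and 2.37 CPM), and NES was higher in SHP77 (17.9 and 95.4 CPM). SOX2, a factor of stem and neural progenitor cells, was at 52.98 CPM in SHP77 and 0 counts in H446.

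In metabolism, glycolysis genes were higher in H446 for 13 of 22, in SHP77 for 1 and within 2-fold for 8 (median -1.03, percentile 0.14). The lactate exporter SLC16A3 was at 1051 CPM in H446 and 6.77 CPM in SHP77, the glucose transporter SLC2A3 at 67.4 and 2.31 CPM and hexokinase HK2 at 93.3 and 9.54 CPM, whereas ALDOC, the neural aldolase, was higher in SHP77 (4.27 and 85.3 CPM). Cholesterol biosynthesis genes were higher in H446 for 11 of 23, in SHP77 for 0 and within 2-fold for 12 (median -0.98, percentile 0.29). Among these, INSIG1 was at 153.5 and 16.3 CPM, IDI1 at 137.9 and 28.8 CPM and PMVK at 40.02 and 79.8 CPM. Serine, one-carbon and amino acid stress genes were higher in SHP77 for 10 of 21, in H446 for 3 and within 2-fold for 8 (median 0.68, percentile 99.5, or 92.8 among random lists not matched on expression). The glutathione-degrading enzyme CHAC1 was at 1.76 and 213.7 CPM in H446 and SHP77, asparagine synthetase ASNS at 14.3 and 530.0 CPM and TRIB3 at 52.3 and 349 CPM. Of 30 nuclear genes of oxidative phosphorylation, 21 lay within 2-fold, 4 were higher in SHP77 and 5 in H446 (median -0.09, percentile 43.8). COX6C was at 47.2 and 198.8 CPM, and UQCRC2 (238.9 and 45.1 CPM), NDUFA9 (154.4 and 43.7 CPM) and SDHA (917 and 310.0 CPM) were higher in H446. Hypoxia genes were higher in SHP77 for 4 of 20, in H446 for 6 and within 2-fold for 10 (median -0.19, percentile 34.8). ADM was at 48.2 and 6.04 CPM, SLC2A1 at 316 and 89.1 CPM and EGLN3 at 27.9 and 127.4 CPM.

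Cancer-testis antigens, normally restricted to germ cells, were higher in SHP77 for 11 of 14 genes and in H446 for 3 (median 4.12, or 5.17 at the bounds, percentile 100). MAGEA4 was at 542.9 CPM in SHP77 and 0.155 CPM in H446, MAGEA10 at 145.6 CPM and 0 counts, MAGEA8 at 79.2 CPM and 1 count and MAGEB2 at 119.5 and 1.55 CPM. MAGEA1 went the other way, at 54.1 CPM in H446 and 0.245 CPM in SHP77. HOX genes, which set position along the body axis, were higher in SHP77 for 11 of 27, in H446 for 9 and within 2-fold for 7 (median 0.43, percentile 56.5), and with the trends removed for 10 and 11 (median -0.03). HOXD8 (0.776 and 78.4 CPM), HOXD11 (0.517 and 53.9 CPM) and HOXD10 (1 count and 30.4 CPM) were higher in SHP77, and HOXA11 was at 30.1 CPM in H446 with 0 counts in SHP77.

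Of 18 targets of antibody and cell therapies, 9 were higher in SHP77, 4 in H446 and 5 lay within 2-fold (median 1.02, percentile 95.1, but -0.22 with a filter at 5 CPM). Besides FOLR1 and DLL3, MSLN, the mesothelin antigen, was at 196.0 and 0.136 CPM in H446 and SHP77, and the neural adhesion molecule NCAM1 was at 0 counts and 121.4 CPM. Of 24 receptor tyrosine kinases, 6 were higher in SHP77, 12 in H446 and 6 lay within 2-fold (median -0.63, percentile 4.12). RET was at 188.6 CPM in SHP77 with 3 counts in H446, and EPHA2 (213.3 and 2.83 CPM) and EPHB4 (69.4 and 3.10 CPM) were higher in H446.

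Chromatin regulators lay within 2-fold for 16 of 26, with 1 higher in SHP77 and 9 in H446 (median -0.36, percentile 17.3). The acetyltransferase CREBBP was at 157.7 and 24.1 CPM, TET2 at 20.6 and 2.47 CPM, ARID2 at 37.9 and 7.07 CPM, SMARCA2 at 62.4 and 16.2 CPM and DNMT3A at 13.4 and 35.1 CPM. Of 20 genes of m6A methylation, 2 were higher in SHP77, 7 in H446 and 11 lay within 2-fold (median -0.19, percentile 36.1). The RNA-binding protein IGF2BP1 was at 55.96 CPM with 2 counts in SHP77, YTHDC2 at 60.2 and 5.55 CPM, METTL14 at 16.1 and 3.51 CPM and ALKBH5 at 93.1 and 258.0 CPM.

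Markers of other cell types gave no uniform picture, and many lay below the filter of 1 CPM in both lines. These were 11 of 16 haematopoietic, 6 of 12 endothelial, 5 of 11 mesothelial and 6 of 11 tuft cell markers. So were 8 of 12 alveolar and club cell, 8 of 12 squamous and basal and 3 of 14 fibroblast markers. The counts here and in the next paragraph cover tested markers only. Of 11 tested fibroblast markers, 1 was higher in SHP77, 5 in H446 and 5 lay within 2-fold (median -0.999, percentile 5.01). COL3A1 was at 60.1 and 1.25 CPM in H446 and SHP77, MMP2 at 45.5 and 2.23 CPM and PDGFRA at 0.233 and 5.38 CPM. Of 4 tested squamous and basal markers, 4 were higher in H446 (median -5.51, or -6.85 at the bounds), with SERPINB5 at 105.7 and 1.28 CPM, TRIM29 at 44.5 CPM and 1 count and DSC3 at 23.02 CPM and 0 counts. Of 4 tested alveolar and club cell markers, 3 were higher in SHP77 and 1 lay within 2-fold (median 4.60, or 6.28 at the bounds), among them the lung lineage factor NKX2-1 at 144.5 CPM against 0.207 CPM in H446. SFTPB was at 3.89 CPM and 0 counts, and AGER at 0.924 and 2.48 CPM, in SHP77 and H446. With the GC and length trends removed AGER passed the rule towards H446 (log2 -0.86 before and -1.54 after).

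Of 6 tested mesothelial markers, 4 were higher in SHP77 and 2 in H446, and the median of 2.05 at percentile 97.8 lost its place apart under several settings. WT1 had 0 CPM in both lines. PRG4 was at 72.4 and 4.09 CPM and DES at 6.36 and 0.336 CPM in SHP77 and H446, and CALB2 at 8.84 CPM and 1 count. MSLN, with the largest difference on this list, went the other way, at 0.136 CPM in SHP77 and 196.0 CPM in H446. Of 6 tested endothelial markers, 4 were higher in SHP77, 1 in H446 and 1 lay within 2-fold (median 1.41, or 2.67 at the bounds, percentile 87.7, and 0.67 with the trends removed). CDH5 had 0 CPM in both lines. CLDN5 was at 265.5 CPM and 3 counts, PECAM1 at 31.4 and 1.53 CPM, EGFL7 at 22.7 and 6.47 CPM and ERG at 1.41 and 18.6 CPM in SHP77 and H446, and EGFL7 lay within 2-fold with the GC and length trends removed (log2 1.66 before and 0.65 after). Of 5 tested haematopoietic markers, 3 were higher in SHP77, 0 in H446 and 2 lay within 2-fold (median 1.03, percentile 56.8), and with the trends removed 1 was higher in each line (median 0.18). PTPRC was at 0.026 CPM in H446 and 0 in SHP77. CD14 reached 9.79 CPM in SHP77 and 1.22 CPM in H446. SPI1 and CD79A stayed below 1.5 CPM in both, and CD68 was at 5.82 CPM in SHP77 and 10.6 CPM in H446. Of 5 tested tuft cell markers, 1 was higher in each line and 3 lay within 2-fold (median 0.91, percentile 51.7). PTGS1 was at 18.1 and 2.41 CPM in SHP77 and H446, and SOX9 at 0 counts and 4.19 CPM.

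**Figure D4:**
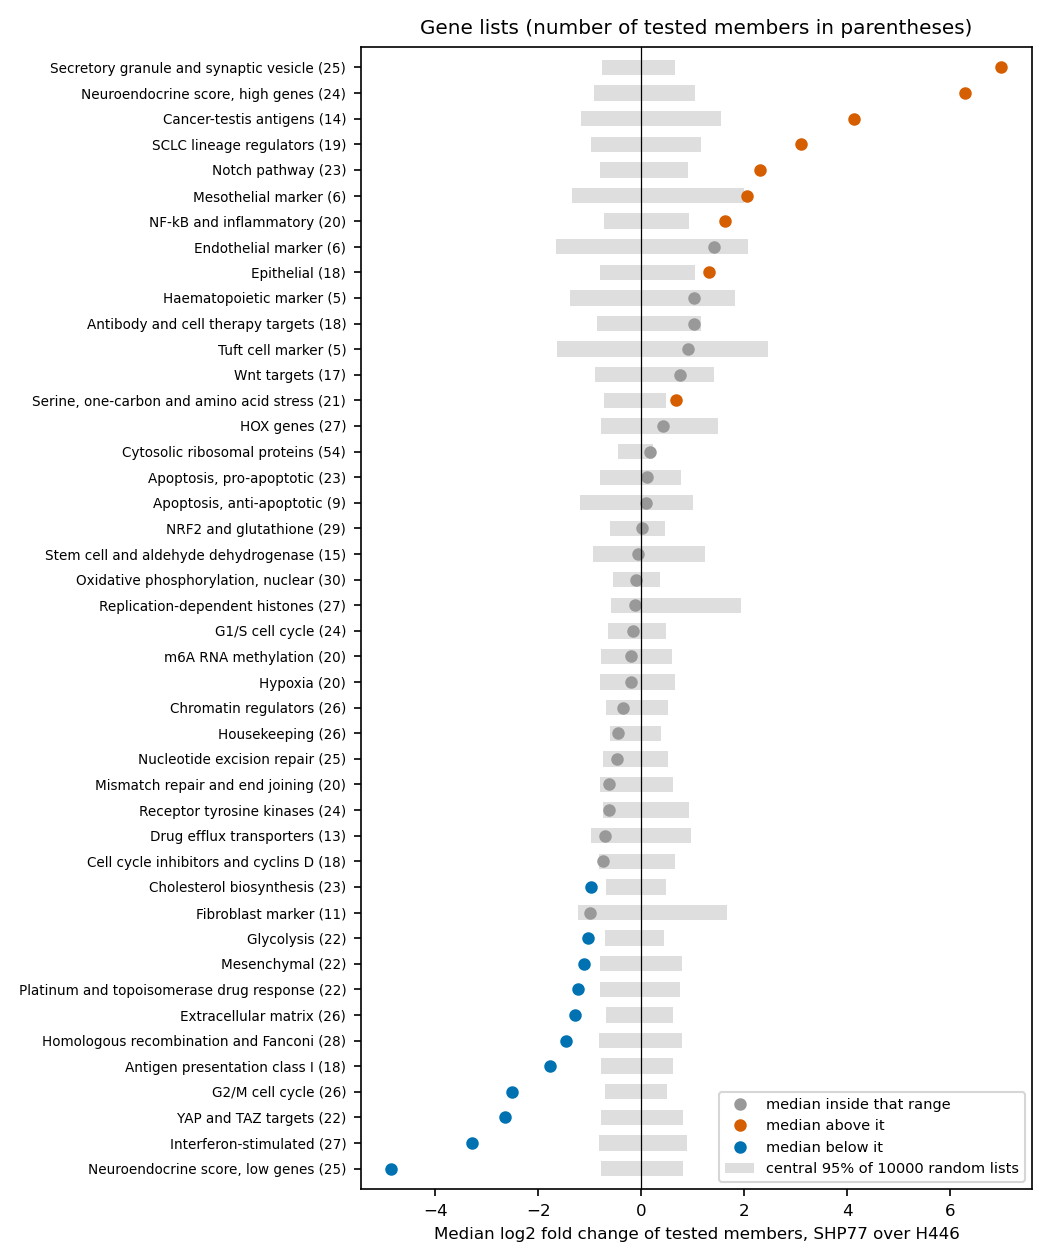
Points give the median log2 fold change, SHP77 over H446, of each list with at least 5 tested members, and grey bars the central 95% of 10000 random lists of the same size and expression. Of 44 lists, 9 stood apart towards SHP77 and 11 towards H446, from 6.996 for secretory granules to -4.85 for the low genes of the neuroendocrine score.

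The most abundant gene held 1.10% of counts in H446 (FTH1, exact 95% interval 1.095 to 1.102) and 1.90% in SHP77 (VGF, 1.898 to 1.907). The 10 most abundant genes held 5.67% of counts in H446 (5.66 to 5.68) and 6.05% in SHP77 (6.05 to 6.06), and the 100 most abundant held 18.5% and 18.7%. Beside VGF and CALCA, the most abundant genes of SHP77 were the ferritin light chain FTL (8653 CPM, and 4504 in H446), ACTB (4598, and 6173) and RPL8 (4281, and 1733). In H446 they were the ferritin heavy chain FTH1 (11387 CPM, and 2482 in SHP77), GAPDH (8165, and 2230), ACTB, EEF1A1 (5912, and 3679) and ENO1 (5459, and 2698). The 54 ribosomal protein genes on the list held 4.08% (4.07 to 4.09) of counts in H446 and 5.36% (5.35 to 5.37) in SHP77, and all 88 genes with a ribosomal protein symbol held 5.18% (5.18 to 5.19) and 6.78% (6.77 to 6.78). Of the 54, 42 lay within 2-fold, with 9 higher in SHP77 and 3 in H446 (median 0.17, percentile 94.2). RPS24 was at 472.7 and 124.0 CPM in H446 and SHP77, RPL14 at 872.7 and 255.6 CPM, RPS27 at 289.5 and 1056 CPM and RPS28 at 121.8 and 371.7 CPM. With the trends removed the balance turned, with 2 higher in SHP77 and 7 in H446 (median -0.30, percentile 70.6). There RPS28 (log2 1.60 before and 0.90 after) and RPL8 (1.30 and 0.39) lay within 2-fold. ENO1 did with plain library totals (-1.02 and -0.91). Of 26 housekeeping genes, 18 lay within 2-fold, 7 were higher in H446 and 1 in SHP77 (median -0.45, percentile 9.82). Among these, TFRC, the transferrin receptor, was at 1016 and 95.7 CPM, B2M at 2349 and 586.8 CPM, POLR2A at 516.0 and 131.6 CPM and GUSB at 80.6 and 243.6 CPM. The 35 replication-dependent histone genes on the list, whose mRNAs mostly lack poly(A) tails, held 0.0277% of counts in H446 and 0.0345% in SHP77, and 17 of 27 tested lay within 2-fold, with 3 higher in SHP77 and 7 in H446 (median -0.12, percentile 13.8). With the trends removed the histone list stood apart, with 13 higher in H446 and 2 in SHP77 (median -0.65, percentile 1.73), while with a filter at 5 CPM, which left 8 genes, the median was 0.25. HIST1H1E was at 1.27 and 13.3 CPM, HIST1H3C at 0.155 and 3.24 CPM and HIST1H4B at 4.22 and 0.652 CPM.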

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

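The alternatives with the longest transcript, the sum over transcripts, the totals implied by the authors' RPKM, the GC and length trends removed and the genes at 0 placed at their bound were chosen after the results were seen, and the others before the data were examined. No list that stood apart changed direction under any of the alternatives run. Named genes were compared only with plain library totals, DESeq2 size factors, a pseudocount of 0.25 and the trends removed. None of their calls reversed there. Over all tested genes with a GC value, directions were compared only with the trends removed, where 0 calls reversed. For the other alternatives, directions of single genes were not compared. However, 15 medians or means of 8 lists that did not stand apart had the opposite sign to the reported median. With the trends removed these were ribosomal proteins (0.17 to -0.30), HOX (0.43 to -0.03), pro-apoptotic (0.11 to -0.08) and stem cell genes (-0.07 to 0.39). With the filter at 5 CPM they were pro-apoptotic genes (-0.08), therapy targets (1.02 to -0.22) and histones (-0.12 to 0.25), and with the mean they were pro-apoptotic (-0.31) and anti-apoptotic genes (0.09 to -0.014). The stem cell list also turned with no filter (0.38), the deeper library thinned (0.028) and the authors' totals (0.0085). Oxidative phosphorylation (-0.09) turned with the authors' totals (0.051), plain totals (0.0089) and upper quartile scaling (0.0033). With the 4-fold rule 1926 genes were higher in SHP77 and 1602 in H446. Apart from that rule, the counts of genes at least 2-fold apart stayed within 1.5 times the reported ones, from 2826 (pseudocount 5) to 4271 (the authors' totals) for SHP77 and from 2873 (pseudocount 5) to 3804 (pseudocount 0.25) for H446. The Pearson r between the libraries was 0.46 with a filter at 5 CPM, 0.54 with a pseudocount of 0.25 and 0.65 with a pseudocount of 5, and the Spearman rho was 0.55 with the filter at 5 CPM.

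Of the 20 lists that stood apart, 16 did so in every alternative. The mesothelial list of 6 genes ended inside the random range with no filter beyond 1 read (median 2.05), a pseudocount of 0.25 (3.32), trends removed (1.35), 10 expression bins (2.05), the mean of members (0.37) and genes at 0 at their bound (2.05). The epithelial list did with the filter at 5 CPM (1.03, with fewer genes tested) and with the mean (0.35), the serine and one-carbon list with unmatched random lists (0.68), and the mesenchymal list with trends removed (-0.57). For lists inside the random range, 7 medians under the alternatives came to lie outside it and 396 did not. They were histones with the trends removed (-0.65), fibroblast markers (-1.56) and cell cycle inhibitors (-0.99) at 5 CPM, fibroblast markers by the mean (-1.69), receptor tyrosine kinases with summed transcripts (-0.9998), haematopoietic markers with no filter (0.35) and therapy targets with unmatched lists (percentile 97.9). Apart from the smaller set of genes at 5 CPM, the cause was not tested. Among the named genes, 13 that were at least 2-fold apart lay inside 2-fold with the trends removed and 202 kept their side of the rule. Another 2, CD68 (-1.33) and AGER (-1.54), came to pass it towards H446. With plain library totals 1, ENO1, lay inside 2-fold (-0.91). There 4 came to pass the rule towards SHP77: FTL (1.05), POLB (1.08), GINS2 (1.06) and PMVK (1.08). With a pseudocount of 0.25, 7 came to pass it, among them POU2F3 (-1.02) and ATOH1 (1.33), which were below the filter. Depth limits the genes near the floor of 3 counts, such as MYCN, NEUROD1 and ABCG2 in SHP77, for which the ratios have wide or open intervals. With a single library per line no alternative can show how far a second culture would differ.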

Other observations

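The gene families, the chromosome neighbourhoods and the test of cycling cells by G1/S genes were chosen after the values were seen, while the tests of the GC and length trend, for the G2/M list too, and of the region around MYC were set before their results. The percentiles of the families below were shaped by that choice and carry no weight as support. The clustered protocadherins, cell-surface proteins that give neurons their identity, were higher in SHP77. Of 13 tested beta-cluster genes, 10 were at least 2-fold higher in SHP77 and 0 in H446, with a median log2 fold change of 2.39 (percentile 98.6 of matched random lists) and a range from -0.55 to 5.40, led by PCDHB2 (0.285 CPM in H446 and 53.3 in SHP77). All 15 alpha-cluster and all 22 gamma-cluster genes were higher in SHP77 (medians 3.61 and 2.44), but their transcripts share constant exons and their values are not separate measurements, ranging only from 3.58 to 4.55 and from 2.22 to 2.57. The same holds for the 9 UGT1A genes, which encode glucuronidating enzymes and share their last exons: each was higher in H446 (median -5.88). SOX11, a factor of neural progenitors, was at 131.6 CPM in SHP77 with 1 count in H446, and of 12 tested SOX genes 7 were higher in SHP77, 4 in H446 and 1 lay within 2-fold (median 1.75, percentile 98.9). Of 10 tested FGF genes, 8 were higher in SHP77 (median 2.32, percentile 98.9), with FGF14 at 74.1 CPM and 3 counts in H446 and FGF9 at 23.95 CPM and 1 count, while FGF2 was higher in H446 (76.9 and 6.42 CPM). Annexins, calcium-dependent membrane-binding proteins, were higher in H446 for 7 of 10 tested genes and in SHP77 for 1 (median -2.13, percentile 0.06). ANXA1 was at 318.1 CPM in H446 and 1.55 CPM in SHP77, ANXA6 at 97.9 CPM and 1 count, and ANXA2 at 1269 and 311.2 CPM.

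Several stretches of neighbouring genes, picked from among the most extreme of 13737 overlapping windows, shared a direction, with the GC and length trends removed and the gene order taken from GRCh38.p14. On chromosome 20, 15 of the 20 tested genes nearest CRLS1 were at least 2-fold higher in SHP77 and 0 in H446, with a median of 2.26, and this stretch holds CHGB and SNAP25. On chromosome 11, 15 of the 20 nearest CD59 were higher in H446 and 0 in SHP77, with a median of -1.82, in a stretch that holds CD44 and RCN1. On chromosome 16, 14 of the 20 nearest COG7 were higher in H446 and 0 in SHP77 (median -1.79), among them PALB2 and PLK1. Whether these follow DNA copy number was not tested.

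The trend with GC content and length could be technical. If fragments rich in GC had been recovered unevenly, GC-rich segments within a gene would hold relatively more SHP77 reads, yet over 136 genes with a usable segment the slope was 0.044 log2 per 10 percentage points of GC (95% bootstrap interval -0.07 to 0.19), below 0.28, which is 0.5 times the slope between the same genes. The slope between these genes was 0.57 (95% bootstrap interval 0.27 to 0.86), and the bound takes no account of that interval. The within-gene interval lay below the interval between genes. For these 136 genes, this argues against uneven recovery of fragments as the whole cause, but not against a part in it. A greater loss of long transcripts in SHP77 remains open, since the correlation with length was -0.13 after the GC trend was removed, beyond the bound of -0.1 set for it. A difference between the lines in which genes they express stays possible as well and was not tested.

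The G2/M list was lower in SHP77 and is poor in GC, so the trend was a candidate explanation. With the trends removed its percentile was 0 among random lists, and 25 of 26 genes were then at least 2-fold higher in H446, so the GC and length trend between the libraries does not account for the whole difference. A lower share of cycling cells in SHP77 would lower G1/S genes too, but their median with the trends removed was -0.49 (SD of members 0.75) against -2.14 for G2/M, above the bound of -1.39 that is the G2/M median plus that SD. That bound was set after both medians were seen, so its outcome was known and it decides nothing about the share. It also presumes that G1/S transcripts fall with the share about as G2/M transcripts do. With the trends removed, 7 of 24 G1/S genes were higher in H446 and 0 in SHP77, so a lower share stays open. Fewer cells in G2 and mitosis alone and a lasting difference between the lines stay open as untested explanations.

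MYC was 8.97 times as abundant in H446, and a gain of its chromosome region may raise its neighbours too. With the GC and length trends removed, MYC itself was at -3.59, and the 20 nearest tested genes had a median log2 fold change of 0.39, towards SHP77, at percentile 74.3 of all such windows, with 2 of them at least 2-fold higher in H446 and 4 in SHP77. As measured, an alternative added after the results were seen, the median was 0.18 at percentile 58.1, with 4 higher in H446 and 6 in SHP77. This argues against a large gain in H446, relative to SHP77, that spans most of these neighbours. The bound set for a gain was percentile 2.5, which a small gain need not reach. For scale, the 20 genes nearest YAP1 had a median of -0.90, yet lay at percentile 9.04. A small gain of the region therefore stays open. A median over 20 genes cannot show a shorter gain. A gain of MYC alone or with a few neighbours, or regulation of the gene, remains open, because shorter stretches were not examined.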
